A study of Mus musculus with 549 samples.

How the data were processed

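Per the submitters' labels, RNA was taken from tibial cartilage, metaphyseal cortical and cancellous bone after marrow removal, and inguinal lymph nodes of male C57BL/6J mice, extracted with RNeasy kits, and sequenced from 3' end libraries. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned to mm10 with STAR, and normalised, with edgeR named as a tool. The deposited values form 12 tables, 1 for each of 4 tissues at 0, 1 and 2 weeks of loading, with 1 column per library: 505 of the 549 samples described have a column, the other 44 are not analysed here, and 0 columns were left out. Columns were matched to samples by the library code that heads each column and ends the sample title, and the treatment and limb of both were the same.

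The deposited values are a normalised signal, in the sense of the authors' normalised read counts. Within each library every value is a whole multiple of 1 step (100% of values within 0.01 of a whole number of steps), so each library's whole reads were recovered by dividing by its step. The steps matched median-of-ratios factors computed within each table (Pearson r across libraries of 0.99999 or more, ratio constant to a coefficient of variation of 0.126% or less), so the authors had scaled each table by itself, and comparisons were made only within a table. Depth is the sum of recovered reads: 3630 to 3557793 per library, with table medians from 1097752 (cancellous bone, 1 week) to 1854724 (cartilage, 1 week). Between 4 and 27 of the 23412 entries of a table name no gene, hold at most 0.247% of reads and were dropped. Symbols were looked up in GENCODE M21 (GRCm38), which holds 92.8% of them (21712), for positions. The reads carry no molecular identifiers that the files show.

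The design was fixed before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend of variance on level, genes kept at a CPM (a share of the column total) of 1 or more in at least as many libraries as the smallest group of the table, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. All groups of a tissue and week shared 1 fit. The animal was inferred from runs of codes in the titles and was a random block (duplicateCorrelation, statmod 1.5.0, on 2000 genes). The correlations of this block ran from -0.001 to 0.142. The limb was a fixed term before loading. In bone after loading a term for the animal code series (plain numbers or codes with a letter) was added. In cartilage and lymph node at 2 weeks that series follows alendronate exactly and could not be a term. Replicate numbers pair the limbs of 1 animal in 28 of 29 cases in cartilage at 1 week and 25 of 25 at 2 weeks. In cortical bone at 1 week they do in 3 of 17, so the animal code served as the block. Among libraries of 100000 reads or more, no pair in a table repeated each other (lowest chi-square per degree of freedom 1.83). The rest were not compared.

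The 44 comparisons of the design were PTH against vehicle before loading, and per tissue at 1 and 2 weeks: loading in vehicle mice (left against right), PTH, alendronate, and PTH then alendronate against vehicle in the loaded limb, and the change of the loading response by PTH. Another 72 secondary comparisons took loading in the other treatments, the contralateral limb, alendronate with and without PTH, and the other interactions. Genes were named by a rule set beforehand: among genes past the threshold with a mean log2 level of at least 3 and a symbol that is not a predicted model, the 10 highest and 10 lowest log2 folds in cartilage and before loading and 5 each elsewhere; the 4 members of smallest p of each list discussed; Acan, Col2a1, Prg4, Mmp13, Mmp3, Col1a1, Bglap, Sost, Acp5, Ctsk and Tnfsf11 always; and with no gene past the threshold the 3 of smallest p. Many other genes that the rule names are given as counts and ranges.

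Fixed lists covered cartilage matrix and chondrocytes, hypertrophy and mineralising cartilage, matrix breakdown and joint inflammation, osteoblast, osteocyte, osteoclast, Wnt pathway and load-response genes, PTH and cAMP targets, immediate early genes, fibrous matrix and TGF-beta response, tendon and ligament, skeletal muscle, erythroid, neutrophil and myeloid precursor, macrophage and dendritic cell, B cell, germinal centre and plasma cell, T cell and natural killer cell, interferon response, adipocyte, endothelial and perivascular cell, lymph node stroma, proliferation, mitochondrial respiration and cytosolic ribosomal proteins. Lists with at least 5 tested members were tested with fry and with cameraPR of limma (preset correlation of 0.01, and an estimated one), adjusted over the lists of a comparison. Lists of clock output genes, clock genes of opposite phase, platelet and eosinophil genes were added after the values before loading had been seen. A list of mitochondrially encoded transcripts had 0 of 11 members in the files and was not tested.

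Alternatives set beforehand were quantile scaling, a pseudocount of 0.25, no filter, no animal block, the replicate number as a block, arrayWeights, 1 limb only, the number series only, no code series term, and leaving out each replicate of groups of up to 5. Alternatives added after the data were seen were edgeR 4.0.16 (quasi-likelihood, TMM factors) on recovered reads, leaving out libraries under 100000 reads, leaving out lymph node libraries high in neutrophil genes, and the vehicle groups alone without a block. Other splits of the same libraries, at most 100 per comparison, were tested the same way. The procedure was tested on simulated data with 200 genes changed in 1 group. Reads were drawn anew from 1 mean profile, with each library's own depth and each gene's own spread. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures. Drug amounts are not given because their stated units are in doubt.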

Results

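Transcript levels were measured by sequencing the 3' ends of messenger RNA in 4 tissues of male mice: tibial cartilage, metaphyseal cortical bone, metaphyseal cancellous bone and the inguinal lymph node. The mice first received parathyroid hormone (PTH), a peptide that builds bone when given intermittently, or vehicle. The left tibia was then compressed cyclically each day while the mice received alendronate, a bisphosphonate that blocks bone resorption by osteoclasts, or vehicle. The right limb was not loaded and served as the contralateral control. Tissues were taken before loading and after 1 or 2 weeks of it. Of 549 samples 505 had values. Before loading there were 16 libraries from 8 mice per treatment in cartilage and in lymph node. Cortical bone had 9 PTH libraries from 5 mice and 7 vehicle libraries from 4 mice, and cancellous bone 8 from 5 and 7 from 4. Each n before loading counts libraries, and both limbs of a mouse are among them. The numbers of mice are inferred from title codes. Afterwards each treatment and limb had 4 to 10 libraries. The groups are named below as vehicle, PTH, alendronate and PTH-alendronate mice.

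The libraries held 3630 to 3557793 reads, with a median of 1552374, and 28 of 505 held under 100000 reads. Of these shallow libraries 14 were of cancellous bone and 9 of cortical bone after 1 week of loading. Cartilage held 2 before loading, and cartilage, cancellous bone and lymph node 1 each at 2 weeks. In the loaded limbs of PTH-alendronate mice at 1 week, 4 of 5 cortical and 5 of 6 cancellous libraries were shallow, with median depths of 36332 and 28758 reads. Levels are given as log2 of the authors' normalised read count plus 1, mean ± SD over libraries. Differences are log2 folds ± SE from limma with the adjusted p.

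**Figure D1:**
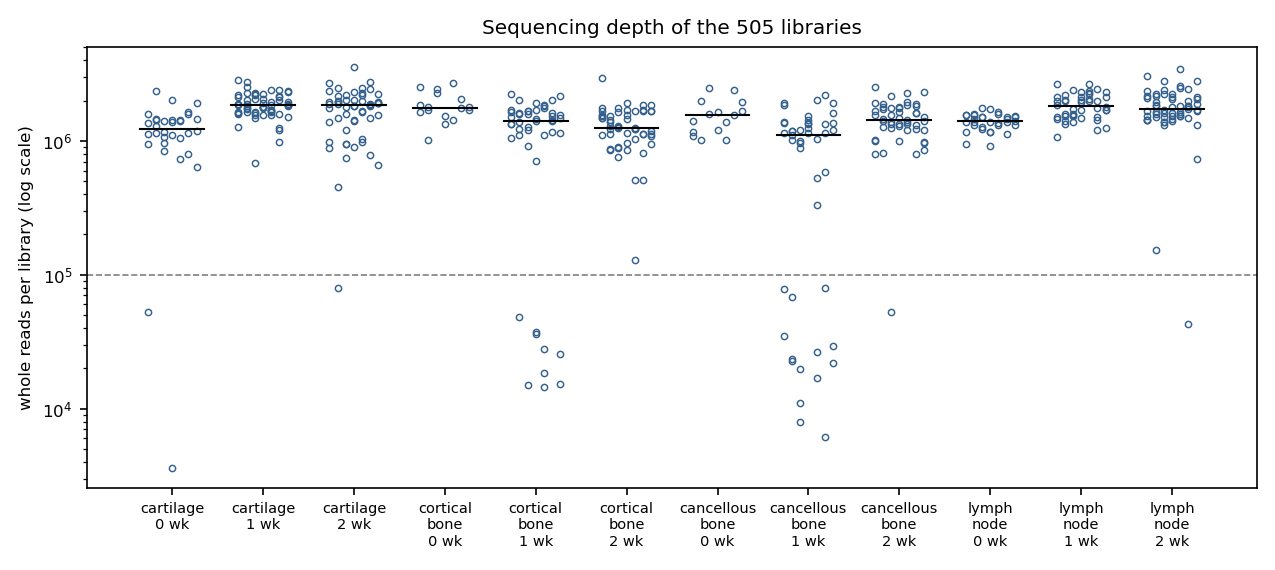
Reads per library (log axis) in each tissue and week, 1 point per library, with the limit of 100000 reads drawn as a line. The 28 libraries under it are mostly bone after 1 week of loading.

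Whether PTH by itself had changed each tissue was read before loading. In cartilage, genes of extracellular matrix and mineralisation were among those higher after PTH, and genes of platelets and granulocytes among those lower. Angptl7, a secreted protein of joint and eye tissue, stood at 8.01 ± 1.48 (SD, n = 16) after PTH and 5.59 ± 1.52 (SD, n = 16) after vehicle, a log2 difference of 2.42 ± 0.49 (adjusted p = 0.0221). Thbs4, of tendon matrix, rose by 1.50 ± 0.29 (adjusted p = 0.0194). Omd, a proteoglycan of mineralised matrix, rose by 1.35 ± 0.31 (adjusted p = 0.0483) and Alpl, the phosphatase needed for mineralisation, by 1.05 ± 0.23 (adjusted p = 0.0346). Cpne8, Cc2d2a, Ccdc80, Nfib and the collagen receptor Ddr2 rose too, by 1.08 to 1.96. The platelet receptors Clec1b, Gp5, Itga2b and Gp1bb and the platelet protein Treml1 fell, with log2 differences of -2.16 to -1.52. So did the eosinophil granule gene Prg2 (-1.60 ± 0.33, adjusted p = 0.0221) and the neutrophil granule gene Ltf (-1.32 ± 0.28, adjusted p = 0.0298). Tmem40, Il2rb and Neurl3 also fell, by -1.69 to -1.53.

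Altogether 11 genes were higher and 15 lower after PTH in cartilage (limma, 12589 tested). Without the 2 shallow libraries, a PTH one of 3630 reads and a vehicle one of 52539, 1116 genes were higher and 784 lower. With edgeR and no animal block 962 and 540 passed on all libraries, including all 26. From the left limbs alone limma called 0 genes (1079 at an unadjusted p under 0.05), from the right limbs alone 1, and with a pseudocount of 0.25 it called 4. It called 1094 after quantile scaling and 3031 with arrayWeights, which weighs libraries by their fit. Among gene lists fixed beforehand, Wnt pathway genes were higher, 21 of 22 of them positive, at an adjusted p of 0.0429 by fry and an adjusted p of 0.1 with an estimated correlation among genes. The p of fry tests whether a list moves one way and does not compare it with other genes. No member passed over all genes and 5 passed when adjusted over the list alone. The 4 of smallest p were Wif1 (0.98 ± 0.26), Wisp1 (0.90 ± 0.26), Sfrp4 (1.33 ± 0.43) and Rspo2 (1.45 ± 0.51). Tendon genes were higher at the same fry adjusted p of 0.0429 (0.108 with the estimated correlation), led by Thbs4, Dcn (1.19 ± 0.32), Col14a1 (0.88 ± 0.32) and Tnmd (1.05 ± 0.47). All 15 neutrophil genes were lower, Ltf, S100a9, Ngp and S100a8 first, 14 adjusted over the list alone and 1 over all genes. Their fry adjusted p was 0.0311, and the adjusted p with the estimated correlation 0.108. The lists of hypertrophy and mineralising cartilage (fry adjusted p = 0.225), osteoblast (0.254), fibrous matrix (0.254) and cartilage matrix genes (0.709) did not pass. Without the 2 shallow libraries they passed (fry adjusted p = 0.00164, 0.00111, 0.00149 and 0.0359), and so did osteocyte genes (0.000501), with an adjusted p of 0.105 to 0.351 by the estimated correlation. In the same fit the lists of proliferation (24 of 24 negative, 16 over all genes, fry adjusted p = 0.00821), erythroid (10 of 10 negative, 8 over all genes, 0.0134) and neutrophil genes (0.00243) were lower, with an adjusted p of 0.105 to 0.161 by the estimated correlation. Lists of endothelial cells (0.000501), lymph node stroma (0.00164) and PTH and cAMP targets (0.0359) were higher there, with 0.105 to 0.364. After quantile scaling the first 3 passed too (fry adjusted p = 0.00365, 0.00658 and 0.00734), with an adjusted p of 0.0949, 0.105 and 0.105 by the estimated correlation, and cartilage matrix genes did not (0.206).

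In the lymph node before loading, PTH raised Cd5l, a macrophage protein, from 5.47 ± 1.12 (SD, n = 16) to 7.04 ± 0.73 (SD, n = 16), by 1.56 ± 0.31 (adjusted p = 0.015). The potassium channel gene Kcnj16 rose by 1.18 ± 0.20 (adjusted p = 0.00708) and Clec1b by 0.98 ± 0.17 (adjusted p = 0.00708). Errfi1, an inhibitor of the epidermal growth factor receptor, fell by 1.01 (SE 0.22, adjusted p = 0.0302). The angiogenic factor Vegfa fell by 0.89 (SE 0.20, adjusted p = 0.0302) and the lipid desaturase Scd1 by 0.85 (SE 0.21, adjusted p = 0.0494). The clock-controlled transcription factors Dbp (0.82 ± 0.20, adjusted p = 0.0406) and Tef (0.65 ± 0.12, adjusted p = 0.00893) were higher. In all, 49 genes were higher and 43 lower (limma, 12667 tested), and edgeR gave 85 and 107, 91 of them shared. With arrayWeights limma called 998, with no filter 60, and from the left or the right limbs alone 0 (992 and 1550 at an unadjusted p under 0.05).

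Few genes passed in bone before loading. In cortical bone 1 gene passed, Hspa5, which encodes the chaperone of the endoplasmic reticulum that folds secreted proteins. It stood at 9.94 ± 0.32 (SD, n = 9) after PTH and 11.43 ± 0.28 (SD, n = 7) after vehicle, a difference of -1.50 ± 0.21 (adjusted p = 0.0111 in limma, also called by edgeR). From the left or the right limbs alone limma called 0 genes (130 and 761 at an unadjusted p under 0.05). The matrix gene Col1a1 was at -0.20 ± 0.50 and the osteocyte gene Sost at -0.86 ± 0.76 there (adjusted p = 1 each). In cancellous bone 0 genes passed in limma (678 at an unadjusted p under 0.05), 2 in edgeR and 320 in limma with arrayWeights. The smallest p belonged to the cell-cycle inhibitor Cdkn1a at -1.51 ± 0.29 and the muscle genes Myh2 at -4.17 ± 0.87 and Pygm at -2.49 ± 0.54 (adjusted p = 0.29 each, n = 8 and 7).

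**Figure D2:**
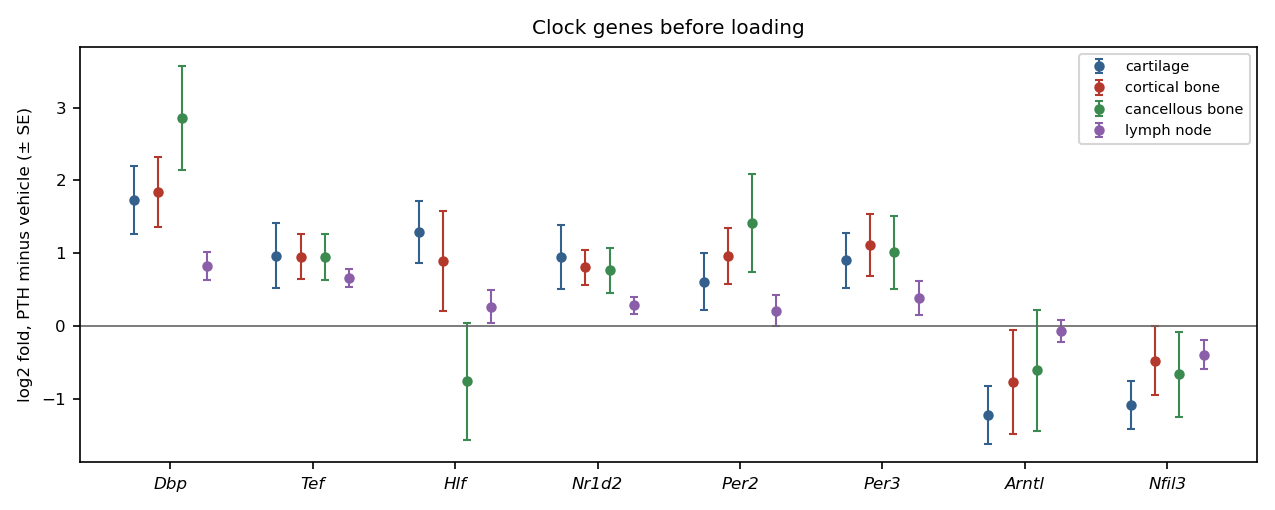
Log2 difference between PTH and vehicle mice before loading, ± SE, for 8 clock genes in 4 tissues. Dbp lies above 0 in each tissue, at 1.73, 1.84, 2.86 and 0.82 in cartilage, cortical bone, cancellous bone and lymph node, and Arntl below it.

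Loading was compared between the left and right limbs of vehicle mice, which asks what the loading used to induce joint degeneration does to each tissue. In cartilage after 1 week fibrous matrix genes, type II collagen, matrix proteases and their inhibitor were higher in loaded limbs. Fat, muscle and respiratory-chain genes were lower there. The mean level of the muscle list ran from 3.02 to 9.72 in loaded and from 4.52 to 12.56 in contralateral libraries. Whether the samples of the 2 limbs held unlike amounts of other tissue was not tested. C1qtnf3, a secreted factor of developing cartilage (chromosome 15, 10952332 to 10980150, GRCm38), stood at 6.78 ± 1.29 (SD, n = 7) in loaded and 2.73 ± 1.33 (SD, n = 7) in contralateral limbs, a difference of 4.04 ± 0.76 (adjusted p = 0.000801). Its lowest loaded library was at 4.36 and its highest contralateral one at 4.08. Type II collagen, Col2a1 (chromosome 15, 97975602 to 98004695), rose from 8.93 ± 0.55 (SD, n = 7) to 10.85 ± 0.71 (SD, n = 7), by 1.92 ± 0.38 (adjusted p = 0.00154). Timp1, which inhibits matrix proteases, rose by 2.38 ± 0.37 (adjusted p = 3.43e-05) and the collagenase activator Mmp14 by 2.05 ± 0.32 (adjusted p = 3.43e-05). The proteases Mmp2 and Mmp13 and the cytokine Il11 rose by 1.91 ± 0.35 (adjusted p = 0.000735), 1.17 ± 0.28 (adjusted p = 0.0123) and 3.05 ± 0.68 (adjusted p = 0.00677). Lrrc15, Cthrc1, Mest, Capn6, the imprinted RNA H19, Tnn, Crabp2 and Fbn2 rose by 2.87 to 3.28. Acan (1.33 ± 0.44, adjusted p = 0.133), Mmp3 (1.60 ± 0.57, adjusted p = 0.185) and lubricin, Prg4 (0.07 ± 0.50, adjusted p = 0.995), did not pass. The fat genes Plin4, Cfd and Cidec fell, with differences of -3.25 to -3.09, as did Ces1d, Cyp2f2 and Abca8a (-3.40 to -2.51). The largest falls were of the muscle genes Myh2 (-5.68 ± 1.21, adjusted p = 0.00407), Ckmt2 (-5.02 ± 1.13) and Myh1 (-4.60 ± 1.16). Nnat fell by 4.39 (SE 0.95, adjusted p = 0.00543), a call that edgeR did not make.

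In all, 148 genes were higher and 45 lower in loaded cartilage at 1 week (limma, 14746 tested; edgeR 141 and 51, 161 shared). With arrayWeights the count was 1063. By fry, 7 of the fixed lists moved, and 6 of them held with the estimated correlation. Of 23 fibrous matrix genes 13 passed over all genes and 16 adjusted over the list alone (fry adjusted p = 0.000727), Col5a1 (2.41 ± 0.30), Col6a1, Col6a3 and Fbn1 first. Of 24 matrix breakdown genes 5 passed and 10 over the list alone (fry adjusted p = 0.000483). Of 20 osteoblast genes 5 passed and 6 over the list alone (fry adjusted p = 0.00352), Cthrc1, Sparc (1.39 ± 0.27), Postn (2.61 ± 0.54) and Col1a1 (1.73 ± 0.36, adjusted p = 0.00364) first. All 14 adipocyte genes were lower, 6 over all genes and 13 over the list alone (fry adjusted p = 0.000727). All 16 muscle genes were lower, 2 and 16 (fry adjusted p = 0.0142), and all 30 respiratory genes, 2 and 18 (fry adjusted p = 0.00352), among them Ndufs1 at -0.76 ± 0.19. The 9 tendon genes were all higher, Fmod (1.56 ± 0.37), Tnc (1.03 ± 0.28) and Scx (1.84 ± 0.69) among them, 2 over all genes and 3 over the list alone. Their fry adjusted p was 0.0495, with an adjusted p of 0.0909 with the estimated correlation. Of 25 cartilage matrix genes 20 were positive (fry adjusted p = 0.11).

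**Figure D3:**
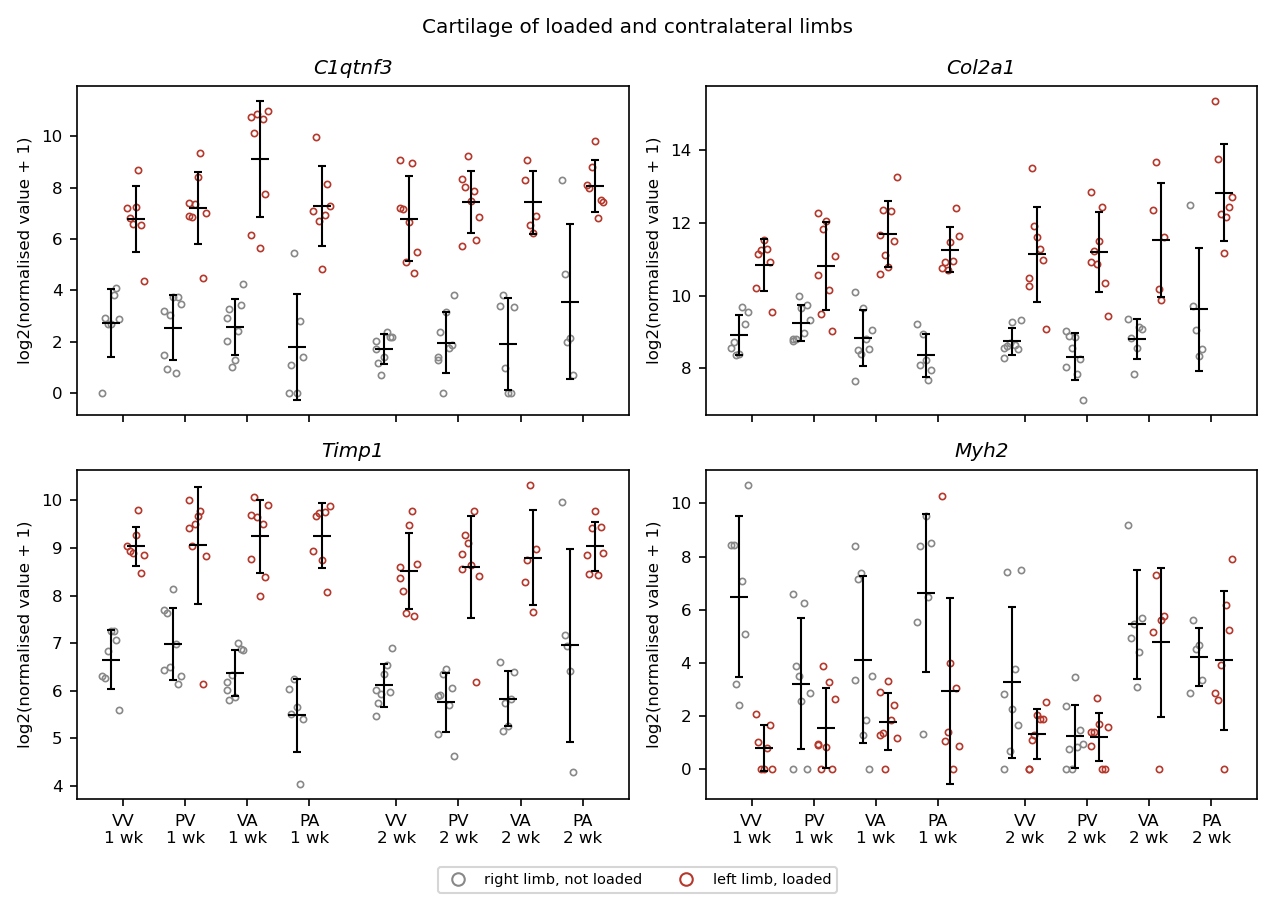
Level of C1qtnf3, Col2a1, Timp1 and Myh2, as log2 of the normalised read count plus 1, in each cartilage library of the contralateral (grey) and loaded (red) limbs of the 4 treatments at 1 and 2 weeks, with mean ± SD. In vehicle mice every loaded library lies above every contralateral one for C1qtnf3 and Timp1 at both times.

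After 2 weeks of loading 81 of the 148 genes higher at 1 week were higher in vehicle cartilage too, where 1.43 are expected by chance (14544 genes tested at both times), and 4 of 43 were lower at both. Type IX collagen chains rose beside them. C1qtnf3 was at 6.79 ± 1.66 (SD, n = 8) against 1.73 ± 0.58 (SD, n = 8), a difference of 5.07 ± 0.70 (adjusted p = 6.59e-06). Col2a1 was at 11.14 ± 1.31 (SD, n = 8) against 8.75 ± 0.37 (SD, n = 8), a difference of 2.40 ± 0.51 (adjusted p = 0.00407). Of these chains Col9a1 and Col9a2 rose by 4.21 ± 0.74 (adjusted p = 0.000252) and 3.24 ± 0.72 (adjusted p = 0.00648), and tenascin-W, Tnn (chromosome 1, 160085029 to 160153580), by 4.01 ± 0.45 (adjusted p = 2.94e-08). H19, Lrrc15, Megf6, Kcnj15, Fbn2 and Ddah1 rose by 3.34 to 4.69. Mmp14 (2.21 ± 0.35, adjusted p = 6.38e-05), Mmp2 (2.47 ± 0.41), Timp1 (2.41 ± 0.43) and Il11 (3.21 ± 0.74) were again higher, while Mmp13 (1.47 ± 0.46, adjusted p = 0.114) and Acan (0.99 ± 0.53) did not pass. Among the genes that fell were Lyve1, of lymphatic vessels and macrophages (-2.64 ± 0.50, adjusted p = 0.000898), Myoc (-3.54 ± 0.77, adjusted p = 0.00549), the red cell genes Car2 (-2.03 ± 0.54) and Bpgm (-1.67 ± 0.41), and Cytl1 (-1.98 ± 0.51), a cytokine of cartilage.

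These made 141 higher and 26 lower genes (limma, 14943 tested; edgeR 267 and 35, 161 shared). The count was 2206 with arrayWeights and 289 after quantile scaling. With the replicate number as a block and only the vehicle libraries in the fit, 880 genes were higher and 550 lower. The fibrous matrix list was higher, 11 of 23 over all genes and 14 over the list alone (fry adjusted p = 0.00223), with Col3a1 (3.16 ± 0.48), Col12a1 (3.06 ± 0.48), Col5a1 and Thbs2 first. So was the matrix breakdown list, 4 and 9 of 24 (fry adjusted p = 0.0027). Both held with the estimated correlation. Endothelial genes were higher, 14 of 16 positive, 5 higher and 1 lower over the list alone and only Lyve1 lower over all genes (fry adjusted p = 0.00937, held with the estimated correlation). The fry calls of 4 other lists were lost with the estimated correlation. Tendon genes were higher, 2 over all genes and 4 over the list alone, at a fry adjusted p of 0.0415 and then an adjusted p of 0.12, led by Fmod and Tnmd (3.00 ± 0.75). Lymph node stroma genes were higher, 2 over all genes and 3 over the list alone, at 0.0231 and then an adjusted p of 0.0748. Those 2 were the collagens Col3a1 and Col1a1. Erythroid genes (0 over all genes, 10 of 10 over the list alone) and proliferation genes (0 and 8 of 24) were lower at 0.0231 and then an adjusted p of 0.065.

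Loading raised many of the same genes in cartilage under the other treatments, by counts that moved with the fit. In PTH mice 344 genes were higher and 99 lower in loaded cartilage at 1 week. In alendronate mice the counts were 652 and 299, and in PTH-alendronate mice 1052 and 478. Of the 148 genes higher in vehicle mice, 117, 137 and 142 were also higher in these groups, where 3.45, 6.54 and 10.6 are expected by chance. At 2 weeks the counts were 409 and 123, 386 and 200, and 492 and 72, and 119, 91 and 96 of the 141 vehicle genes were shared against 3.86, 3.64 and 4.64 by chance. After quantile scaling these counts were 664 and 334, 462 and 311, and 264 and 93, and by edgeR 685 and 273, 408 and 267, and 45 and 25. The last, of PTH-alendronate mice, was 85 and 3 without contralateral PTH-alendronate replicate 4, a library of 80131 reads, and 1 and 0 with arrayWeights. That of alendronate mice was 577 and 358 without that library, which shares the spread. With the 2 groups alone and the replicate number as a block 0 genes passed in limma in PTH-alendronate mice (1098 at an unadjusted p under 0.05) and 0 in alendronate mice (1187). At 1 week this fit with a block gave 176 and 67, 994 and 572, and 68 and 9 in PTH, alendronate and PTH-alendronate mice, and arrayWeights 851 and 555, 1594 and 1226, and 901 and 290. Cartilage matrix genes as a list were higher with loading in PTH mice at 2 weeks, 11 of 25 over all genes (fry adjusted p = 0.000721, and 0.0128 with the estimated correlation). Skeletal muscle transcripts varied widely among cartilage libraries. The list's mean level was 5.73 ± 2.88 (SD, n = 7) in loaded and 9.49 ± 3.15 (SD, n = 7) in contralateral limbs of vehicle mice at 1 week. At 2 weeks it was 4.90 ± 1.34 (SD, n = 8) and 5.99 ± 2.31 (SD, n = 8).

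**Figure D4:**
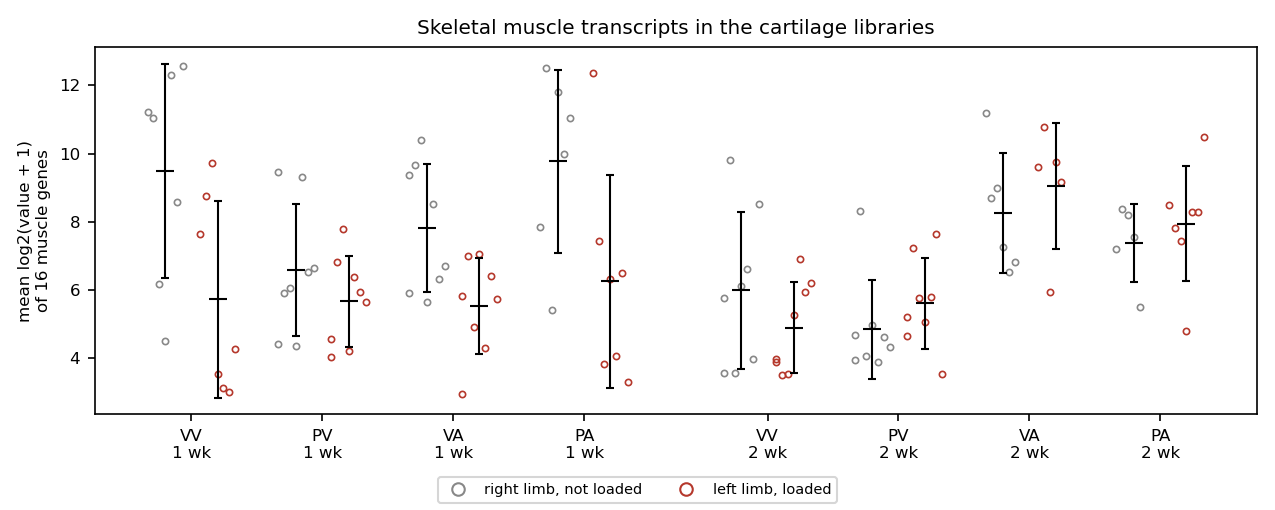
Mean level of the 16 skeletal muscle genes (log2 of the normalised read count plus 1) in each cartilage library by treatment and limb at 1 and 2 weeks, with mean ± SD. Loaded limbs of alendronate mice at 2 weeks lie at 9.05 ± 1.84 and those of vehicle mice at 4.90 ± 1.34.

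In bone of vehicle mice few genes passed for loading in limma. In cortical bone at 2 weeks the interstitial collagens Col3a1 (1.95 ± 0.47) and Col6a3 (1.72 ± 0.42) had among the smallest p (adjusted p = 0.469 each, n = 7 and 9). There 0 genes passed in limma (1498 at an unadjusted p under 0.05), 15 with arrayWeights and 129 in edgeR, both collagens among them. In PTH mice at that time 8 genes were higher and 0 lower, Col3a1 (2.61 ± 0.47, adjusted p = 0.0106) and Col16a1 (2.38 ± 0.46, adjusted p = 0.0106) with them. The count was 199 with arrayWeights and 4 in edgeR. In vehicle mice at 1 week 0 genes passed in cortical bone in limma (969 at an unadjusted p under 0.05; 1 or 2 without any one of loaded vehicle replicates 1, 2 and 4) and 75 in edgeR, 104 with arrayWeights, 13 after quantile scaling and 19 without the shallow libraries. S100a4, a calcium-binding protein of migrating cells, was at 1.86 ± 0.43 (adjusted p = 0.351). In cancellous bone at 1 week 1 gene was lower, the potassium channel gene Kcna6 (-3.79 ± 0.73, adjusted p = 0.0465), chosen after its values were seen because its mean level of 0.87 lies under the limit for naming. Here edgeR called 4 genes and arrayWeights 328. Kcna6 was not called without loaded replicates 2, 3 or 4 or contralateral replicates 4 or 5, which gave 2, 2, 1, 0 and 0 genes. At 2 weeks 0 passed there in limma (521 at an unadjusted p under 0.05) and 0 in edgeR, Dusp10 having the smallest p at 2.68 ± 0.62. In PTH-alendronate mice at 1 week cortical bone had 17 higher and 1154 lower genes, with 4 of 5 loaded libraries shallow. The counts were 81 and 182 after quantile scaling, 0 and 8 with arrayWeights and 29 and 0 in edgeR. Without the shallow libraries 1 loaded library is left, so no count is given. From these 2 groups alone 0 passed in limma (1837 at an unadjusted p under 0.05), or 0 with the replicate number as block (4764). Cancellous bone of these mice had 4 and 8, with 5 of 6 loaded libraries shallow. It had 6 and 13 in edgeR and 0 with arrayWeights in limma (1446 at an unadjusted p under 0.05).

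In the lymph node of the loaded side of vehicle mice at 1 week, granulocyte and red cell genes were lower than on the other side. The granule genes Ltf (-3.90 ± 0.86) and Camp (-4.10 ± 0.92) had an adjusted p of 0.104 each (n = 6 and 4). Counts were 0 in limma (2019 at an unadjusted p under 0.05) and 568 in edgeR, 563 of them lower. Neutrophil genes (13 of 14 over the list alone, 0 over all genes) and erythroid genes (7 of 7 and 0) were lower at a fry adjusted p of 0.01. Fibrous matrix (16 of 23 over the list alone), osteoblast (10 of 14), cartilage (7 of 12), hypertrophy, osteocyte, osteoclast, tendon and proliferation (16 of 24) genes were lower at 0.01 to 0.0252. B cell (8 of 13) and T cell (11 of 20) genes were higher at 0.0244 and 0.0311. With the estimated correlation the adjusted p of these 12 lists ran from 0.0589 to 0.0966. These differences rest on contralateral replicate 1, whose neutrophil list stood at 10.51 against 2.79 to 5.34 in the other contralateral libraries. Without it 0 genes passed and 441 did at an unadjusted p under 0.05. Without replicate 2, 3 or 4 232, 431 and 529 genes passed. At 2 weeks 0 genes passed in limma (2090 at an unadjusted p under 0.05) and 34 in edgeR, with 168 by arrayWeights, Malat1 at -1.10 ± 0.25 (adjusted p = 0.201) with the smallest p. Cartilage (14 of 14 negative) and tendon genes (5 of 5) were lower at a fry adjusted p of 0.00919, with an adjusted p of 0.54 for both by the estimated correlation. After quantile scaling their fry adjusted p was 0.865 and 0.0828.

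Whether PTH given beforehand left a difference in the loaded limb was read from PTH against vehicle mice. The one gene of moderate level that passed was Gpnmb, a glycoprotein of osteoclasts, osteoblasts and macrophages, in cortical bone at 2 weeks. It stood at 4.04 ± 0.88 (SD, n = 7) after PTH and 6.54 ± 0.96 (SD, n = 7) after vehicle, a difference of -2.49 ± 0.45 (adjusted p = 0.0145). There 1 gene passed in limma (2822 at an unadjusted p under 0.05) and 173 in edgeR, 168 of them lower, with 86 by arrayWeights. Quantile scaling, which moved the median of all genes by -0.413, gave 18 higher and 4 lower genes, and the libraries of the number series of animal codes alone gave 867 and 406. Osteocyte genes were higher in this comparison, 14 of 15 positive, 3 over the list alone and 0 over all genes (fry adjusted p = 0.0183, but an adjusted p of 0.398 with the estimated correlation). Of them the phosphate regulator Phex was at 1.93 ± 0.44 and Mepe at 1.10 ± 0.35. In cancellous bone at 2 weeks 1 gene was higher, Cadm2 (2.27 ± 0.43, adjusted p = 0.0331), an adhesion gene with a mean level of 0.36 that was chosen after its values were seen. There edgeR called 0 genes, arrayWeights 428, and 726 passed in limma at an unadjusted p under 0.05. Cadm2 was not called without PTH replicate 1, 2 or 3, which left 1, 0 and 3 genes, while 4 passed without replicate 4.

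In loaded cartilage the count between PTH and vehicle mice depended on the weighting of libraries. With arrayWeights limma called 538 genes at 1 week and 1120 at 2 weeks. Without weights, at 1 week 0 genes passed in limma (1286 at an unadjusted p under 0.05) and 0 in edgeR. Ier2, an immediate early gene, was at 1.52 ± 0.32 and Myl10 at -2.41 ± 0.49 (adjusted p = 0.102 each, n = 8 and 7). At 2 weeks 0 genes passed in limma (470 at an unadjusted p under 0.05) and 0 in edgeR, and Col2a1 (0.06), Acan (0.39) and Mmp13 (0.62) had an adjusted p of 1. In cortical bone at 1 week the counts were 0 in limma (377 at an unadjusted p under 0.05; 1 without vehicle replicate 4) and 1 in edgeR, Hoxd8 having the smallest p (-1.95 ± 0.46, adjusted p = 1). In cancellous bone they were 0 in limma (256; 1 without vehicle replicate 2 or 4) and 1 in edgeR, with Lamb3 at -0.96 ± 0.24. In the lymph node 0 passed in limma at 1 week (1388 at an unadjusted p under 0.05; 1 without PTH replicate 4) and 0 in edgeR. Cdc14a, Sema3d and the cAMP phosphodiesterase Pde4d (-0.97 ± 0.20) lay at adjusted p values of 0.0907 to 0.0928. At 2 weeks 0 passed there in limma (747 at an unadjusted p under 0.05) and 0 in edgeR.

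Alendronate given during loading was compared with vehicle in the loaded limb. In cartilage at 2 weeks contractile genes of skeletal muscle were far higher and osteocalcin was lower. Titin, Ttn, stood at 12.47 ± 1.29 (SD, n = 5) with alendronate and 6.75 ± 1.25 (SD, n = 8) with vehicle, a difference of 5.72 ± 0.81 (adjusted p = 1.62e-05). Xirp2, Mybpc1, Neb, Myh4, Atp2a1, Tnnt3, Mybpc2, Sh3bgr and Pvalb rose by 4.55 to 5.18. Osteocalcin, Bglap, which osteoblasts secrete into mineral, fell by 3.02 (SE 0.85, adjusted p = 0.0203), and Prg4 rose by 2.46 ± 0.64 (adjusted p = 0.0121). The decoy receptor Il1r2 fell by 3.59 (SE 0.71, adjusted p = 0.00104), with Insig1, Fcgr2b, Ndst2, Ifitm6, Bglap2, Dfna5, Chn1 and Chkb at -3.35 to -2.74. In all, 547 genes were higher and 528 lower (limma; edgeR 891 and 527, 898 shared). The count was 3943 with arrayWeights. Without alendronate replicate 3 the count was 708, 471 higher and 237 lower. At 2 weeks every library of mice given alendronate has a letter code. Every vehicle library of cartilage and lymph node has a plain number, so code series and alendronate cannot be told apart there. In bone the series term rests on vehicle and PTH mice alone.

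Muscle genes were higher in that comparison as a list, 14 of 16 over all genes and 16 over the list alone (fry adjusted p = 0.000771). Ribosomal protein genes were lower, 10 and 11 of 28, Rpl7 (-1.42 ± 0.26), Rpl18, Rplp0 and Rps19 first (fry adjusted p = 0.000771). With the estimated correlation these 2 lists had an adjusted p of 0.0839 and 0.204. Macrophage, interferon and respiratory genes were lower at a fry adjusted p of 0.0119 each, and each list had an adjusted p of 0.482 with the estimated correlation. Among them Lyz2 (-2.12 ± 0.50), Flt3, Cd68, Oas2 (-2.25 ± 0.61), Cxcl9 and Cox4i1 (-1.05 ± 0.26) were lower, and Mrc1 (0.90 ± 0.29) and Bst2 (1.91 ± 0.57) higher. Over all genes these 3 lists held 3 lower members each of 19, 22 and 30, and over the list alone 6, 4 and 6. After quantile scaling, which moved the median of all genes by 0.121, the interferon list had a fry adjusted p of 0.0697. At 1 week 1 gene passed in cartilage, the actin regulator Fam101b, at 0.81 ± 0.15 (adjusted p = 0.024, n = 8 and 7). Here edgeR called 0 genes, arrayWeights 26, and 735 passed in limma at an unadjusted p under 0.05.

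In the lymph node of the loaded side at 2 weeks alendronate went with the largest count of the study. Clec2d, a ligand of natural killer cell receptors (chromosome 6, 129180615 to 129186534), stood at 8.34 ± 0.41 (SD, n = 8) with alendronate and 3.76 ± 1.58 (SD, n = 8) with vehicle, a difference of 4.58 ± 0.53 (adjusted p = 1.14e-08). The endothelial receptor Gpr182 (4.35 ± 0.51), the death effector Bax (4.12 ± 0.55), the small nucleolar RNA Snord89 (4.09 ± 0.70) and the interferon-induced Bst2 (3.94 ± 0.53) rose, and so did the protease Mmp3, by 2.63 ± 0.44 (adjusted p = 1.48e-05). Erdr1 (-4.08 ± 0.78), Mien1 (-3.11 ± 0.47), Csrp1, Midn and Mfge8 (-2.60 ± 0.39), a secreted protein that links apoptotic cells to phagocytes, fell, and the acid phosphatase Acp5 fell by 1.04 (SE 0.21, adjusted p = 0.000151). In all, 1544 genes were higher and 2004 lower (limma, 14162 tested; edgeR 1899 and 2525, 2962 shared), and 5583 passed with arrayWeights. B cell genes were lower on balance, 3 higher and 6 lower of 13 both over all genes and over the list alone, with Blk (-1.40 ± 0.20), Cd22 and Cr2 among them (fry adjusted p = 0.00334, but an adjusted p of 0.73 with the estimated correlation). The median of the list was -0.63, and -0.25 after quantile scaling. Tendon genes were higher, Dcn (0.91 ± 0.24) and Tnc (0.96 ± 0.34) among 5 (fry adjusted p = 0.0066, but 0.73 with the estimated correlation). The code series limits this comparison as it does that of cartilage. In the contralateral limb at 2 weeks alendronate mice had 580 higher and 407 lower genes in the lymph node and 217 and 312 in cartilage. These became 1106 and 931, and 348 and 484, after quantile scaling. In edgeR they were 1329 and 1546, and 407 and 186. Without contralateral PTH-alendronate replicate 4 (80131 reads) cartilage had 345 and 594.

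Elsewhere few genes passed for alendronate in limma, and the count moved with the fit. In cortical bone at 2 weeks Arhgef18, a regulator of the actin cytoskeleton, was lower, at 4.26 ± 0.61 (SD, n = 5) against 6.22 ± 1.09 (SD, n = 7), a difference of -2.07 ± 0.38 (adjusted p = 0.0236). There edgeR called 234 genes and 2305 passed in limma at an unadjusted p under 0.05. Arhgef18 was not called without alendronate replicate 1, 4 or 6, which left 0, 0 and 1 genes, and 2 and 4 genes passed without replicates 3 and 7. In cancellous bone at 2 weeks 0 genes passed in limma (1083 at an unadjusted p under 0.05) and 1 in edgeR, with 42 by arrayWeights and Neurl2 at 3.47 ± 0.74 (adjusted p = 0.112). Leaving out each alendronate replicate gave 1 gene, or 25 without replicate 6. At 1 week 0 genes passed in limma in cortical bone (583 at an unadjusted p under 0.05) and 1 in edgeR. In cancellous bone 0 passed in limma (317; 1 without vehicle replicate 2), 13 in edgeR and 120 with arrayWeights, and in the lymph node 0 in limma (1977) and 0 in edgeR. The lysosomal pump gene Atp6v1b2 (3.18 ± 0.76), the matrix gene Pcolce2 (4.74 ± 1.25) and the estrogen receptor Esr1 (-1.87 ± 0.38) had among the smallest p there, at an adjusted p of 0.666, 1 and 0.158.

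PTH then alendronate was compared with vehicle. In loaded bone at 2 weeks the combination went with lower osteoblast genes, given a series term from vehicle and PTH mice. In cancellous bone Bglap stood at 3.02 ± 2.63 (SD, n = 5) against 7.64 ± 1.05 (SD, n = 7) in vehicle mice, a difference of -4.14 ± 0.87 (adjusted p = 0.0307). The sphingomyelinase Smpd3, needed for mineralisation (-4.90 ± 0.75, adjusted p = 0.000378), Col1a1 (-3.11 ± 0.67, adjusted p = 0.0307), Col1a2 (-2.87 ± 0.60, adjusted p = 0.0307), Col11a1 (-4.32 ± 0.92), the citrate transporter Slc13a5 (-4.04 ± 0.84) and Hibch (-3.81 ± 0.87) fell too. The receptor of macrophages and osteoclast precursors Csf1r rose by 2.33 ± 0.51 (adjusted p = 0.0312), with Uchl1, S100a4 and Hdac7 rising by 1.49 to 3.46. The count was 6 higher and 13 lower (limma; edgeR 62 and 6, 9 shared, without a call for Bglap or Smpd3). Quantile scaling, which moved the median of all genes by 0.32, gave 8 and 7. Without PTH-alendronate replicate 2, 3, 4, 6 or 7 the count was 107, 53, 1, 115 and 1. Of 20 osteoblast genes 5 were lower over all genes and 9 over the list alone (fry adjusted p = 0.0362, and an adjusted p of 0.316 with the estimated correlation). Germinal centre and plasma cell genes, Sdc1 first (-2.56 ± 0.60), were lower at the same fry p, 3 of 14 over the list alone (adjusted p = 0.398 with the estimated correlation).

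In cortical bone at 2 weeks 17 of 20 osteoblast genes were negative, 7 over the list alone and 0 over all genes (fry adjusted p = 0.0256, and 0.00229 with the estimated correlation, which was 0.0544 after quantile scaling). The osteoblast membrane gene Ifitm5 was at -2.40 ± 0.53 and Smpd3 at -2.24 ± 0.51 (adjusted p = 0.0918 each, n = 4 and 7). Osteoclast genes were higher, 15 of 17 positive and 5 over the list alone, Slc9b2 (2.23 ± 0.64) first (fry adjusted p = 0.00836, but an adjusted p of 0.234 with the estimated correlation). So were respiratory genes, 26 of 30 positive and 11 over the list alone. Their fry adjusted p was 0.0383, but the adjusted p 0.465 with the estimated correlation and 0.0544 by fry after quantile scaling. Over all genes 0 passed in limma (2162 at an unadjusted p under 0.05) and 329 in edgeR, with 3 without PTH-alendronate replicate 3 and 1 without replicate 8.

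At 1 week the combination in cortical bone gave 17 higher and 609 lower genes in limma (n = 5 and 4) and 0 in edgeR. Depth differed between the groups, 4 of the 5 PTH-alendronate libraries being shallow. Without the shallow libraries 1 PTH-alendronate library is left, so no count is given for that fit. Quantile scaling moved the median of all genes by 0.965 and gave 2 and 58. The fall of the clock repressor Nr1d1 was -5.62 ± 1.09 (adjusted p = 0.00467) with all libraries and -0.75 without the shallow ones. Without PTH-alendronate replicate 1, 2, 3, 4 or 5 the count was 2292, 992, 330, 361 and 391, and without vehicle replicate 3 it was 2780. Omd (-4.22 ± 0.82, adjusted p = 0.00467), Col6a3 (-4.12 ± 0.91), Thbs2 (-4.30 ± 0.97), Nin, Fkbp7, Nhlrc2 and Ube2o were lower and Cdkn2d (3.94 ± 0.87), Picalm, Csnk2b, Zeb2 and Atp6v1b2 higher. Without the shallow libraries, which leaves 1 PTH-alendronate library, Zeb2 was at -0.23. With arrayWeights 0 genes passed in limma (2369 at an unadjusted p under 0.05). Osteoblast (3 over all genes, 13 over the list alone), fibrous matrix (3 and 9), tendon (2 and 6) and germinal centre genes (1 and 5) were lower at a fry adjusted p of 0.0269 each. Their adjusted p values were 0.8, 0.839, 0.703 and 0.985 with the estimated correlation, and 0.0757, 0.0757, 0.0757 and 0.566 by fry after quantile scaling. In cancellous bone at 1 week 0 genes passed in limma (1875 at an unadjusted p under 0.05) and 0 in edgeR, with the acute-phase gene Serpina3n at -4.52 ± 1.02 (adjusted p = 0.0922). The count was 20 genes without vehicle replicate 2 or 3 and 1 without replicate 1 or 4.

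In cartilage at 2 weeks muscle genes were higher with the combination, Ttn by 3.98 ± 0.74 (adjusted p = 0.00148), Neb by 4.04 ± 0.82 (adjusted p = 0.00451), and Mybpc1 by 4.22 ± 0.90. Code series and treatment cannot be told apart here. Xirp2, Atp2a1, Tnnt3, Mybpc2, Mb, Pvalb and Myh1 rose by 3.42 to 3.67, and Bglap fell by 3.30 (SE 0.77, adjusted p = 0.0124, n = 7 and 8). Aplnr, Bglap2, Erdr1, Coq10a, Frat1, Ppp2r5d, Insig1, Ap5s1 and Gfod1 fell, at -2.77 to -2.18, and Col2a1 was at 1.70 ± 0.53 (adjusted p = 0.072). The count was 179 higher and 148 lower (limma; edgeR 390 and 204, 296 shared), and 277 and 365 after quantile scaling. It was 1768 with arrayWeights. Muscle genes were higher, 9 of 16 over all genes and 16 over the list alone (fry adjusted p = 0.0204, and an adjusted p of 0.124 with the estimated correlation). At 1 week 2 genes were higher, the kinase gene Csnk1g2 (0.94 ± 0.19) among them, and 2 lower, Nelfcd (-1.54 ± 0.31) and Mppe1 (-2.78 ± 0.56, adjusted p = 0.0319), the last chosen after its values were seen. There edgeR called 2 genes, arrayWeights 225, and quantile scaling 10 higher and 28 lower.

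In the lymph node at 2 weeks 477 genes were higher and 207 lower after PTH and alendronate (limma, with 685 and 654 in edgeR, 607 shared, n = 8 and 8). Code series and treatment cannot be told apart here either. The count was 3386 with arrayWeights and 1161 after quantile scaling. Snord89 rose by 3.49 ± 0.70 (adjusted p = 0.00106), Clec2d by 2.87 ± 0.53 (adjusted p = 0.000405), the growth factor Gdf11 by 2.59 ± 0.47 and Bax and Ppia by 2.44 each. The sterol regulator Insig1 fell by 2.22 (SE 0.38, adjusted p = 0.000112), with Mien1, Ces2e, Rrad and Btbd2 at -1.93 to -1.64. At 1 week 0 passed in limma (1523 at an unadjusted p under 0.05), 65 with arrayWeights and 0 in edgeR, Ube2k having the smallest p at -0.70 ± 0.14 (adjusted p = 0.193). Between PTH-alendronate and alendronate mice, which share the code series, 1 gene was higher and 1 lower in the lymph node, Tef (1.17 ± 0.22, adjusted p = 0.015) and Akap2 (-0.91 ± 0.16, adjusted p = 0.0101). After quantile scaling 39 genes were higher and 12 lower there, without loaded vehicle replicate 3 (42853 reads) 43 and 12, with arrayWeights 22 and 16, and by edgeR 60 and 24. The counts were 6 and 6 in cartilage (13 and 10 after quantile scaling, 24 and 11 without contralateral PTH-alendronate replicate 4, 1 and 1 in edgeR), among them the lipid transporter Abca3 (2.56 ± 0.55, adjusted p = 0.0291), and 0 and 2 in cancellous bone, Smpd3 (-4.68 ± 0.78, adjusted p = 0.00256) and Vps4a (0 and 1 after quantile scaling or with arrayWeights, 0 and 3 without the shallow library, 1 and 0 in edgeR). At 1 week cortical bone had 20 higher and 2335 lower genes between them, where 4 of 5 PTH-alendronate libraries are shallow. Leaving out the shallow libraries leaves 1 with PTH and alendronate, so no count is given for it. The counts were 62 and 186 after quantile scaling, 1 and 101 with arrayWeights and 14 and 2 in edgeR. The code series is not shared there, as 4 of 9 alendronate libraries are of the letter series and none of the others. From the number series only the counts were 6 and 974.

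The study's own question was whether PTH changes the response to loading, tested as the difference of the limb differences. Osteoblast genes as a list had a more positive limb difference in PTH than in vehicle mice in cortical bone at 2 weeks. The median of the list was 1.48, against 0.343 for all genes. The list did not pass for loading in vehicle mice there. The test does not tell in which treatment or limb the difference arose. Of 20 genes 19 were positive, 12 over the list alone and 0 over all genes (fry adjusted p = 0.00676, and 0.0288 with the estimated correlation). The phosphatase Phospho1 was at 2.65 ± 0.77, Bglap at 1.86 ± 0.66 and Col1a2 at 1.52 ± 0.51 (adjusted p = 0.844, n = 7 to 9 per group). As single genes 0 passed there in limma (779 at an unadjusted p under 0.05) and 0 in edgeR. Cartilage showed 0 genes in limma and in edgeR at 1 week (584 at an unadjusted p under 0.05) and at 2 weeks (488; 7 with arrayWeights), where the difference for Col2a1 was -0.36 and 0.48. Cortical bone at 1 week had 0 in limma (255) and 0 in edgeR, and the lymph node at 2 weeks 0 (196) and 0. Cancellous bone had 0 in limma at 1 week (643) with 2 in edgeR and 147 with arrayWeights. It had 0 in limma at 2 weeks (338; 1 without PTH loaded replicate 4) with 0 in edgeR and 1 with arrayWeights. In the lymph node at 1 week Adamtsl1, an extracellular matrix protein, had a difference of 3.74 ± 0.67 (adjusted p = 0.0192), chosen after its values were seen. There edgeR called 67 genes and 1275 passed at an unadjusted p under 0.05. That gene was not called without PTH loaded replicate 6, PTH contralateral replicates 1, 3 or 5 or vehicle contralateral replicates 1 or 2, each leaving 0 genes, and 5 genes passed without vehicle contralateral replicate 3.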

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

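The tests of depth and of single values in this part were applied to every group of 4 to 10 libraries by 1 criterion, and of the values here only those of edgeR and those without shallow or neutrophil-rich libraries come from tests chosen after the result was seen. A library was singled out when its gap to the nearest other library of its group, divided by the group's range, exceeded Dixon's 95% critical value, which chance does in about 1 in 20 groups.

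By depth, 14 of 68 groups had a library apart. Low ones were cortical bone loaded PTH replicate 2 (15249 reads), alendronate replicate 6 (25812) and vehicle replicate 3 (14397), all at 1 week, lymph node loaded alendronate replicate 8 (153802) and vehicle replicate 3 (42853) at 2 weeks and alendronate replicate 5 (1214382) at 1 week, and cartilage loaded vehicle replicate 7 at 1 week (686257) and contralateral vehicle replicate 5 at 2 weeks (954702). High ones were cancellous bone loaded PTH-alendronate replicate 4 (1360285) and cortical bone loaded PTH-alendronate replicate 1 (1694566) at 1 week, cartilage loaded PTH-alendronate replicate 4 (3557793) and contralateral PTH replicate 7 (2773538) at 2 weeks, cortical bone loaded PTH replicate 7 at 2 weeks (2965916), and cortical bone vehicle replicate 1 before loading (2419427). In loaded cortical bone at 1 week the count after PTH and alendronate went from 626 to 2780 without vehicle replicate 3 and to 2292 without PTH-alendronate replicate 1.

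Among 20 groups of this size whose gene means are printed, 5 had a library apart. C1qtnf3 was at 0 in contralateral vehicle cartilage replicate 1 at 1 week, where the other libraries reach up to 4.08. Bglap was at 5.60 in loaded vehicle cancellous bone replicate 5 at 2 weeks. Arhgef18 was at 8.56 in loaded vehicle cortical bone replicate 5 at 2 weeks, above the group's mean of 6.22. Clec2d was at 0 in loaded vehicle lymph node replicate 3 at 2 weeks, the library of 42853 reads, without which the difference with alendronate was 4.05, and at 7.44 in loaded alendronate replicate 8, the library of 153802 reads.

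The response to loading differed between treatments, by the test of the difference itself, for few genes, all chosen after their values were seen. At 1 week in cartilage PTH then alendronate changed it for 2 genes, the transfer RNA thiolase Ctu1 (3.50 ± 0.63, adjusted p = 0.0101 in limma) and Chic1 (3.90 ± 0.73, adjusted p = 0.0109), with 0 by edgeR and 1001 at an unadjusted p under 0.05. In cancellous bone at 1 week it changed it for 2 genes, the inositol phosphatase Inpp5a (-6.07 ± 1.15, adjusted p = 0.0335) and Pcolce2 (7.36 ± 1.46, adjusted p = 0.04), with 1 by edgeR and 1235 at an unadjusted p under 0.05. That count was 0 in limma with arrayWeights (1680 at an unadjusted p under 0.05) and 3 after quantile scaling. Without the shallow libraries 1 loaded PTH-alendronate library is left, so no count is given. PTH changed it for 1 gene in lymph node at 1 week, Adamtsl1 (3.74 ± 0.67, adjusted p = 0.0192), which was 0 genes without the lymph node library high in neutrophil genes. Alendronate changed it for 1 gene in cartilage at 2 weeks, Ppp1r14c (3.44 ± 0.62, adjusted p = 0.0112). That count was 0 in limma after quantile scaling (915 at an unadjusted p under 0.05), 0 in edgeR, 2 without the shallow library and 30 with arrayWeights. No explanation was tested for these.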

How the results depend on the processing

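The edgeR test (no animal block) and the fits without shallow or neutrophil-rich libraries were chosen after the results were seen. So was that of the vehicle groups alone without a block. The other alternatives were set beforehand. Of the values of the 44 counts under alternatives other than leaving out a library, 250 stayed within 1.5 times the reported count and 110 moved further. Counts of 0 that stayed 0 are among the 250, and 26 of the 44 reported counts are 0. Among the named genes 10557 values kept direction and side of the threshold, 308 came to pass it and 300 no longer passed it. Another 367 changed sign with no call under either setting. Only 1 with a call changed sign: Zeb2 in cortical bone after PTH and alendronate at 1 week. It was 3.20 and became -0.23 without the shallow libraries, 4 of the 5 treated libraries being among them. Except where named, the cause was not tested. Below, PTH, alendronate and the combination stand for the comparisons with vehicle in the loaded limb, loading for the vehicle mice, and interaction for the change of the loading response by PTH.

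With arrayWeights counts before loading were 3031 in cartilage, 320 in cancellous bone and 998 in lymph node. In cartilage at 1 week they were 1063 (loading), 538 (PTH), 26 (alendronate) and 225 (combination), and at 2 weeks 2206, 1120, 3943 and 1768, with 7 for the interaction. In cortical bone at 1 week they were 104, 3, 1 and 0, and at 2 weeks 15 (loading) and 86 (PTH). In cancellous bone they were 328 (loading), 2 (PTH), 120 (alendronate) and 147 (interaction) at 1 week and 428 (PTH), 42 (alendronate) and 1 (interaction) at 2 weeks. In lymph node they were 1 (PTH), 65 (combination) and 0 (interaction) at 1 week and 168 (loading), 5583 (alendronate) and 3386 (combination) at 2 weeks.

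With edgeR the counts that moved were 1502 in cartilage, 2 in cancellous bone and 192 in lymph node before loading. In cartilage they were 0 (alendronate) and 2 (combination) at 1 week and 302 (loading) and 594 (combination) at 2 weeks. In cortical bone they were 75 (loading), 1 (PTH), 1 (alendronate) and 0 (combination) at 1 week and 129, 173, 234 and 329 at 2 weeks. In cancellous bone they were 4, 1 and 13 (loading, PTH, alendronate) with 2 for the interaction at 1 week, and 0 (PTH), 1 (alendronate) and 68 (combination) at 2 weeks. In lymph node they were 568 (loading) and 67 (interaction) at 1 week and 34 (loading) and 1339 (combination) at 2 weeks.

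Quantile scaling gave 1094 genes in cartilage before loading, 0 (alendronate) and 38 (combination) in cartilage at 1 week, 289 (loading) and 642 (combination) at 2 weeks, 13 (loading) and 60 (combination) in cortical bone at 1 week and 22 (PTH) at 2 weeks, 2 (loading) in cancellous bone at 1 week and 0 (PTH) and 2 (alendronate) at 2 weeks, and 1161 (combination) in lymph node at 2 weeks. It moved the median of all genes by 0.519 (loading), -0.199 (PTH), -0.242 (alendronate) and -0.286 (interaction) in cortical bone at 1 week, by -0.349 (loading), -0.288 (alendronate), 0.612 (combination) and 0.643 (interaction) in cancellous bone at 1 week, and by 0.185 (loading) and -0.179 (combination) in lymph node at 2 weeks, and the largest shift among all comparisons of a table was 1.18, in cortical bone at 1 week. All 50 list calls by fry kept their direction and 42 their adjusted p under 0.05. With cameraPR 44 of the 50 passed at the preset correlation and 11 at the estimated one.

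Without libraries under 100000 reads the counts that moved were 1900 in cartilage before loading, 19 (loading) and 8 (combination) in cortical bone at 1 week, 4 (loading), 1 (PTH) and 9 (combination) in cancellous bone at 1 week, 502 (combination) in cartilage and 38 (combination) in cancellous bone at 2 weeks. With log2(value + 0.25) they were 4 in cartilage before loading, 2 in cancellous bone (loading, 1 week), 1 in lymph node (loading, 1 week) and 0 in cancellous bone (PTH, 2 weeks). With no filter they were 60 in lymph node before loading, 0 (loading) and 1 (alendronate) in cancellous bone at 1 week, 2 in lymph node (interaction, 1 week), 2 (alendronate) and 2 (combination) in cortical bone at 2 weeks, and 4 (PTH) and 8 (combination) in cancellous bone at 2 weeks.

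From the left limbs alone 0 genes passed before loading in cartilage, cortical bone and lymph node, and from the right limbs alone 1, 0 and 0; each holds about one limb's libraries, so fewer samples. Without the animal as a block 142 genes passed in lymph node before loading, 0 in cancellous bone (loading, 1 week) and 29 in cancellous bone (combination, 2 weeks). With the replicate number as a block and the vehicle groups alone 1430 genes passed for loading in cartilage at 2 weeks and 0 in cancellous bone at 1 week; the same groups alone with no block gave 1544 and 0, so the step from 167 came with the smaller set of libraries and not with the block. From the number series alone the counts were 344 in cortical bone (combination, 1 week), 0 (loading) and 1 (alendronate) in cancellous bone at 1 week, 1273 in cortical bone (PTH, 2 weeks) and 0 in cancellous bone (PTH, 2 weeks). Without the code series term they were 0 in cancellous bone (loading, 1 week) and 4 in cortical bone (alendronate, 2 weeks), and without neutrophil-rich lymph node libraries 0 for the interaction at 1 week.

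Leaving out each library of groups of up to 5 in turn moved 56 of 132 counts. The ranges were, at 1 week in cortical bone, 0 to 2 (loading), 0 to 1 (PTH), 0 to 0 (alendronate and interaction) and 330 to 2780 (combination), in cancellous bone 0 to 4, 0 to 1, 0 to 1 and 1 to 20, with 0 to 0 for the interaction, and in lymph node 0 to 529 (loading), 0 to 1 (PTH) and 0 to 5 (interaction). At 2 weeks they were 708 to 1041 (alendronate) in cartilage, 0 to 4 (alendronate) and 0 to 3 (combination) in cortical bone, and 0 to 4 (PTH), 1 to 25 (alendronate), 1 to 115 (combination) and 0 to 1 (interaction) in cancellous bone. The libraries behind these ends are named with the results. Leaving out cortical bone loaded alendronate replicate 2 at 1 week, whose code stands where right limbs stand, left 0 genes for loading, PTH and alendronate.

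How much could be found differed between comparisons and tools. The simulation took each library's depth and each gene's spread from the data and added no differences between animals. In simulated data with 200 changed genes, limma recovered 14.6% of 2-fold and 62.2% of 4-fold changes in cartilage before loading, where edgeR recovered 55.2% and 93.9%. For loading limma recovered 39.2% and 58.6% in cartilage at 1 week, 38% and 65.7% in lymph node at 2 weeks, but 0% and 5% in cortical bone at 1 week, where edgeR recovered 1% and 42%. For PTH it recovered 20.2% and 59.6% in cartilage at 1 week and 0% and 19.4% in cancellous bone at 2 weeks. False calls were 11 of 107 in limma and 6 of 101 in edgeR for loading in cartilage at 1 week and 2 of 21 and 1 of 19 for PTH in cancellous bone at 2 weeks, each above the share of 0.05 aimed at. In limma they were 1 of 76 in cartilage before loading, 3 of 82 for PTH in cartilage at 1 week, 0 of 5 in cortical bone and 2 of 105 in lymph node.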

Other observations

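The comparison of the cartilage genes with the code series, the clock gene lists, the platelet and eosinophil lists and the comparison with 1-week tables below were chosen after the results were seen; the test of the lymph node genes against the code series, that of marrow and blood lists and the splits were set before.

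Before loading, genes that the molecular clock drives had a median above 0 after PTH in all 4 tissues. As a list they passed by fry in cortical bone (10 of 10 positive, fry adjusted p = 0.0461, and 0.00165 with the estimated correlation) and lymph node (0.0482, but an adjusted p of 0.355 with the estimated correlation). They did not pass in cartilage (0.113) or cancellous bone (0.129), where Hlf was at -0.76 and Bhlhe41 at -0.38. Without the 2 shallow libraries of cartilage the fry adjusted p there was 2.06e-05. Dbp differed by 1.73 ± 0.47 in cartilage, 1.84 ± 0.48 in cortical bone, 2.86 ± 0.72 in cancellous bone and 0.82 ± 0.20 in lymph node, while Arntl, of opposite phase, was at -1.22, -0.77, -0.61 and -0.07. With all libraries only lymph node Dbp of these had an adjusted p under the threshold in limma, 0.0406. Without the shallow libraries Dbp was at 2.20 (adjusted p = 0.000182) and Arntl at -1.32 (adjusted p = 0.0112) in cartilage. The median of clock output genes lay above that of the opposite-phase genes by 0.96, 1.07, 1.40 and 0.33, over 0.1 in 4 of 4 tissues. A different time of day of collection in the 2 treatments predicts such gaps, but the lists were chosen because of these genes, so the gaps do not weigh for it. Time of day and PTH acting on the clock cannot be told apart, because no label gives the hour.

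Platelet and granulocyte genes were lower after PTH in cartilage before loading. The added platelet list had a median of -1.41 (5 of 14 lower over all genes, 13 over the list alone) and the eosinophil list one of -1.60 (1 of 9 and 7), at a fry adjusted p of 0.00362 each and an adjusted p of 0.0517 with the estimated correlation. Clock output genes had a median of 0.90 there. If PTH cartilage samples held less marrow and blood, all such cells should be lower: without the 2 shallow libraries the medians of the erythroid, neutrophil, B cell and T cell lists were -0.947, -1.12, -0.624 and -0.565, the last being the highest, so the explanation may hold. A change in blood formation under PTH, the biological explanation in the design, was not tested and stays open.

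Alendronate went with 3548 genes in lymph node and 1075 in cartilage at 2 weeks, where all alendronate codes carry a letter. Bone at 2 weeks holds vehicle and PTH mice of both series, which lets the series difference be measured: 199 genes were higher and 301 lower with a letter in cortical bone and 0 in cancellous bone. A batch marked by the series predicts that the alendronate differences follow it. Across called lymph node genes r was 0.38 and 0.418 with the 2 bone tables, above the bound of 0.3 set beforehand for a batch. Genes are not independent replicates. Over all genes r was 0.228 and 0.24. Across called and all genes it was 0.479 and 0.446, and 0.328 and 0.286, in the contralateral limb. For PTH then alendronate in the loaded limb it was 0.351 and 0.414, and 0.229 and 0.211. At 1 week, where all lymph node libraries are of 1 series, r over all genes was -0.172 and -0.23 for alendronate in the loaded limb, -0.001 and 0.033 in the contralateral limb and -0.313 and -0.294 for PTH then alendronate. The lymph node differences are therefore consistent with a batch, although r of that size, with the opposite sign, arises in this tissue without a change of series. Of 10 named lymph node genes 6 had the sign of the series difference in each bone table, and 1 and 0 passed there. In cartilage r across called genes was -0.028 and 0.154, and 0.054 and 0.277 for PTH then alendronate. Neither pair meets the bound for a batch or that against it, 0 or less in both. Signs matched the series for 71.8% and 63.1% of alendronate genes in cartilage, against 71.2% and 70% in lymph node. In the contralateral limb these were 58.9% and 55.5%, against 76.3% and 73.3%. The design confounds batch and alendronate in either tissue, and an effect of alendronate itself stays open.

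Skeletal muscle transcripts were not set against an explanation. Their mean level in loaded cartilage at 2 weeks was 9.05 ± 1.84 (SD, n = 5) in alendronate, 7.95 ± 1.69 (SD, n = 7) in PTH-alendronate, 5.62 ± 1.33 (SD, n = 8) in PTH and 4.90 ± 1.34 (SD, n = 8) in vehicle mice, and in contralateral limbs 8.25 ± 1.75, 7.37 ± 1.14, 4.85 ± 1.45 and 5.99 ± 2.31. In lymph node 3 libraries had a neutrophil list level over 8: contralateral vehicle replicate 1 at 1 week (10.51, with an erythroid level of 9.43), loaded vehicle replicate 3 (9.48) and contralateral vehicle replicate 5 (9.02) at 2 weeks.

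Over the 44 comparisons the fixed lists passed by fry in 50 of 1098 tests. The tendon list passed in 7 comparisons, osteoblast in 6, fibrous matrix in 4, and mitochondrial respiration and skeletal muscle in 3 each. The lists of B cell, cartilage matrix, erythroid, germinal centre, matrix breakdown, neutrophil, osteoclast, osteocyte and proliferation genes passed in 2 each. Those of T cell, Wnt pathway, adipocyte, ribosomal protein, endothelial, hypertrophy, interferon, lymph node stroma and macrophage genes passed in 1 each. PTH and cAMP targets passed in 0, with a smallest fry adjusted p of 0.0543, and immediate early genes in 0, with 0.0705.

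Other splits of the same libraries were tested for each count, up to 100 each. Each comparison was taken by itself, with no allowance for the 44 made. In 12 of them a share of splits under 0.05 gave as many genes, which makes chance alone unlikely for each. Only the real split gave as many, 1 of 100, before loading in cartilage (26 genes against at most 14 in other splits), cortical bone (1 against 0) and lymph node (92 against 5), and at 2 weeks for loading in cartilage (167 against 62), alendronate in cartilage (1075 against 263) and lymph node (3548 against 2611), and PTH then alendronate in cartilage (327 against 116), cancellous bone (19 against 2) and lymph node (684 against 3). In cartilage at 1 week 2 of 64 splits gave as many for loading (193 against 201), and 2 of 100 for alendronate (1 against 1) and for PTH then alendronate (4 against 6). Chance cannot be excluded for 6 other counts: PTH then alendronate in cortical bone at 1 week (24 of 100, 626 against 7366), loading in cancellous bone at 1 week (15 of 40, 1 against 4), PTH on the loading response in lymph node at 1 week (6 of 100, 1 against 1), and at 2 weeks PTH (7 of 100, 1 against 225) and alendronate (40 of 100, 1 against 2380) in cortical bone and PTH in cancellous bone (11 of 100, 1 against 4). Each count of 0 is met by every split, 32, 35, 40, 64 or 100 of them. Some splits called many more genes than the real one, up to 7366 and 947 in cortical bone at 1 week, 369 in cancellous bone at 1 week, 2554 and 2380 in cortical bone at 2 weeks, and 1158 for loading in lymph node at 2 weeks. What set these splits apart was not tested.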
